A study of Homo sapiens with 12 samples.

How the data were processed

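Messenger RNA was sequenced in 12 libraries from KYSE150 and KYSE410, established human esophageal squamous carcinoma lines. Each line was kept at 21% oxygen (normoxia) or 0.5% oxygen (hypoxia), with 3 libraries per line and oxygen level. RNA was taken with TRIzol and captured on VAHTS mRNA beads before library preparation, per the labels' protocols. The labels give a time point of 48 h for hypoxia and 0 for normoxia, while the series' design text gives the same incubation for both oxygen levels, so how long the normoxic cultures were kept is not settled. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which could be technical.

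The submitters' processing notes list bcl2fastq 2.20, fastp 0.22.0, HISAT2 2.2.1 and the genome build hg38, without the roles of the tools. The quantifier, the annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of FPKM values per line (fragments per kilobase of transcript, scaled to library size), with 30703 and 30106 gene symbols, of which 26115 were in both. The unit was inferred from the values: columns summed to between 351501 and 425094, and FPKM multiplied by the length of the longest GENCODE transcript summed to between 0.956 and 1.050 times the total that this unit implies. Whether the values move in steps of whole reads was not tested. The depth of each library is unknown, and no counting interval is given. Between 22787 and 24667 genes were above 0 per library.

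The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined, with a branch for counts and a branch for normalized values, of which the latter was used. Within each line, limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend) was fitted to log2(FPKM + 1) for genes with a mean of at least 1 FPKM, which kept 12692 genes in KYSE150 and 12054 in KYSE410. A log2 change is on this scale and understates the change of genes with low values. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference between lines in response (interaction of line and oxygen) and the normoxic difference between lines came from a joint fit of all 12 libraries over 12653 genes. The tables were deposited separately, so levels set across lines assume that FPKM is comparable between them. Of 40 preset gene lists, those with a tested member (40 and 38) were tested with camera at a preset inter-gene correlation of 0.01; genes of a list missing from the tables were not analysed here. Gene positions and transcript lengths came from GENCODE 29 on hg38, and 96.1% and 96.3% of tested genes had a length.

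The genes named in the text follow a preset rule. It took 20 preset genes, the 8 largest rises and falls per line among called genes with a mean of at least 5 FPKM and non-overlapping groups, up to 4 called members per list, the 6 largest differences in response each way, and the 5 largest normoxic differences each way. For the difference in response, non-overlap was read as groups apart within both lines. Some genes that the rule takes are not reported here.

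Each fit was tested on simulated values made from the real means and spreads, with 200 changed genes. In KYSE150 (12692 genes) 47.8% of changes of 0.5 and 100.0% of changes of 1 on the log2 scale were recovered, against 92.5% and 100.0% in KYSE410 (12054 genes). For the difference in response (12653 genes) the shares were 32.8% and 95.5%, and for the normoxic difference 71.6% and 100.0%. Between 1.1% and 4.9% of the simulated calls were false. The simulated changes were few and balanced in direction, with independent spread and no scaling shift or shared library deviation. In the real data most tested genes were called and the balance of calls moved with scaling. These shares are therefore not error rates of the real calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read and plotted the values. Alternatives covered scaling, filters, the pseudocount, the threshold, the replicate number as a block, transcript length and GC content, and leaving out each library. Count-based tools were not run, because the values are not counts.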

Results

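The series profiled gene expression in KYSE150 and KYSE410, established lines of human esophageal squamous carcinoma, after culture in 0.5% or 21% oxygen, to describe the response to hypoxia. There were 3 libraries in each of the 4 groups, and values were deposited as FPKM with unknown depth. Same-group libraries correlated at r = 0.9786 to 0.9964 on the log2 scale across genes. The lowest values involved KYSE150 normoxia replicate 2, whose log2 difference from the other KYSE150 normoxia libraries had an SD of 0.339 and 0.369, against 0.153 to 0.197 for all other same-group pairs. Its deviation from its group also fell with transcript length (Spearman rho -0.631 across genes, which are not independent replicates). In the labels, KYSE150 libraries carry sample-sheet numbers 50 to 55, while KYSE410 carries 38 to 40 in normoxia and 56 to 58 in hypoxia. Library sets are inferred here from these numbers alone. In KYSE410 oxygen cannot be told apart from library set so inferred.

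In KYSE150, hypoxia raised classical low-oxygen genes. NDRG1, a stress-responsive differentiation gene (chromosome 8, 133237171 to 133302022), went from 71.1 ± 5.89 to 1072 ± 22.7 FPKM (SD, n = 3), a log2 change of 3.90 ± 0.09 (SE). CA9, a carbonic anhydrase used as a hypoxia marker, rose by 2.85 ± 0.07, from 9.80 ± 0.292 to 76.8 ± 4.24 FPKM. BNIP3, a mitophagy receptor, rose by 2.92 and ADM, which encodes the vasoactive peptide adrenomedullin, by 3.27. SLC2A1, LDHA and PGK1, for glucose uptake and glycolysis, rose by 1.86, 1.99 and 2.18. ANKRD37, KDM3A, ANGPTL4, P4HA1, LOX, EGLN3 and PDK1 also rose (limma, adjusted p at most 4.124e-05). VEGFA, a well-known HIF target, had 44.4 ± 1.75 FPKM in normoxia and 48.9 ± 1.93 in hypoxia, a log2 change of 0.14 that did not pass (adjusted p = 0.118); it passed when the values were scaled by the median of ratios (0.292, adjusted p = 0.0085). HIF1A and EPAS1, which encode the oxygen-regulated HIF subunits, changed by -0.49 and -0.90, while ARNT, their partner, rose by 0.48. The HIF1A call was lost after scaling by the median of ratios (adjusted p = 0.0712) and without normoxia replicate 1 or 3 or hypoxia replicate 1 or 2 (adjusted p = 0.0506 to 0.0696).

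The largest rises in KYSE150 were EDN2 (endothelin 2), from 0.388 FPKM in normoxia to 50.7 ± 7.01 in hypoxia, PCK1, TXNIP, ANKRD37, NDRG1, PFKFB4, HILPDA and INSIG1, with log2 changes of up to 5.22. Among the largest falls, SLC7A11, the cystine transporter, CHAC1, PSAT1 of serine synthesis and ASNS, asparagine synthetase, had log2 changes of -4.38 ± 0.23, -4.27 ± 0.12, -4.24 ± 0.07 and -4.13 ± 0.08. ASNS went from 247 ± 13.7 to 13.2 ± 0.738 FPKM. The tRNA synthetase genes MARS1 and AARS1 changed by -3.47 and -3.34, PSPH by -3.37 and SESN2 by -3.29. The rule for the largest rises and falls took only genes whose groups did not overlap. Over all genes, 2981 were higher and 4925 lower, and 570 and 980 of them changed by at least 1 on the log2 scale. The groups did not overlap for 69.6% of tested genes, against 10% by chance. The median log2 change of all genes was -0.13, and scaling by the median of ratios moved it to 0.00 and the calls to 3905 higher and 3815 lower, a share of higher calls of 50.6% in place of 37.7%. List medians called relative are given relative to the median of all genes.

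**Figure D1:**
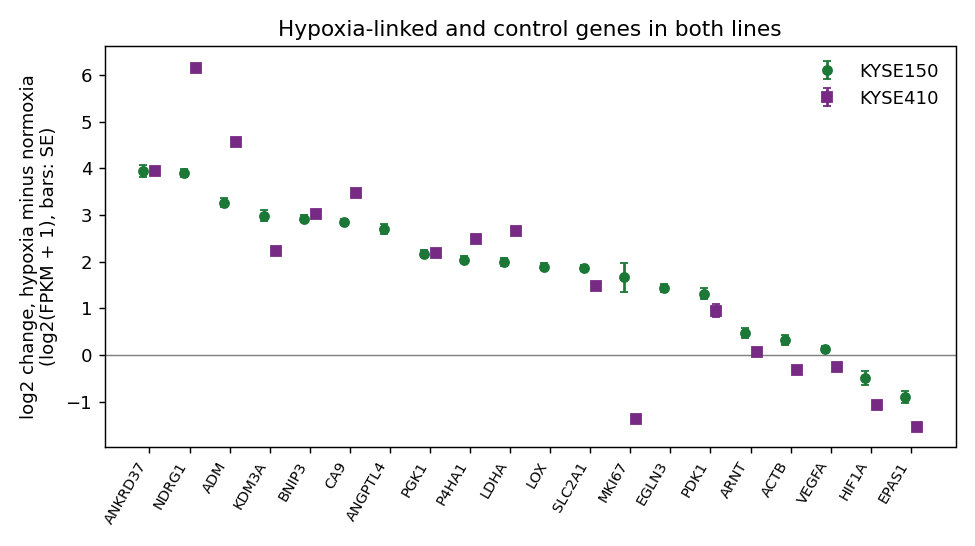
Log2 change (hypoxia minus normoxia, log2(FPKM + 1)) of the preset genes in KYSE150 (circles) and KYSE410 (squares), 3 libraries per group, with bars for the SE. NDRG1 changed by 3.90 in KYSE150 and 6.14 in KYSE410, and MKI67 by 1.67 and -1.37; EGLN3, ANGPTL4 and LOX have no KYSE410 point because their mean was under 1 FPKM.

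Of 22 glycolysis genes in KYSE150, 21 rose and 0 fell, with a median 1.57 above that of all genes (camera adjusted p = 3.855e-14, adjusted p = 0.156 with an estimated correlation). PFKFB4, SLC2A3, ALDOC and ENO2 rose by 2.88 to 3.65. The integrated stress response list, targets of the transcription factor ATF4, had 28 of 30 genes lower and 1 higher, with a relative median of -1.93 (adjusted p = 3.213e-11, adjusted p = 0.156 with an estimated correlation). Of 54 G2/M genes, 48 rose and 1 fell (relative median 1.03, adjusted p = 3.171e-17, adjusted p = 0.0387 with an estimated correlation). ANLN, CDCA3, CDC20 and HJURP, which act in mitosis and cytokinesis, rose by 2.82, 2.48, 2.08 and 1.92. Of 48 G1/S genes, 13 rose and 19 fell, and the list was not called (adjusted p = 0.904), with 18 higher and 11 lower after median-of-ratios scaling. Of 23 cholesterol synthesis genes, 19 rose and 1 fell (relative median 0.84, adjusted p = 2.206e-09, adjusted p = 0.181 with an estimated correlation), among them INSIG1, MSMO1 and MVD.

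In the same line, 26 of 38 MYC target and ribosome biogenesis genes fell, such as ODC1 (-2.40) and RRS1 (-2.19), and 2 rose (adjusted p = 8.476e-04, adjusted p = 0.446 with an estimated correlation). Of 23 NRF2 targets, 15 fell and 2 rose, with TXNRD1 changed by -2.28 and SRXN1 by -1.90 (adjusted p = 0.0044, adjusted p = 0.370 with an estimated correlation). Mitochondrially encoded mRNAs fell in 11 of 13 cases, CYTB by 2.02, and their share of all FPKM was 5.95 to 7.73% in normoxia and 3.50 to 4.12% in hypoxia (adjusted p = 0.0014, adjusted p = 0.497 with an estimated correlation). The hypoxia metagene had 28 of 48 genes higher and 13 lower (adjusted p = 1.869e-06, adjusted p = 0.370 with an estimated correlation). Adjusted over the list alone, the counts of the lists named for KYSE150 were identical, except that 20 G1/S genes and 16 NRF2 targets were lower. In all, 16 of 40 lists were called and 1 held with an estimated correlation. Another grouping of the same 6 libraries also gave 16 called lists, so the number of called lists does not set the real grouping apart; for 10 of the 16 lists the real grouping gave the smallest p of the 10 groupings, among them every list named in the preceding paragraph as called, the hypoxia metagene and the MYC target list, but not the NRF2 or mitochondrial list.

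In KYSE410, the low-oxygen markers that could be tested rose, apart from VEGFA. NDRG1 reached 1194 ± 60.4 FPKM in hypoxia (SD, n = 3), a log2 change of 6.14 ± 0.08, and HILPDA, a lipid droplet protein gene, went from 7.13 ± 0.373 to 472 ± 9.42 FPKM, a change of 5.86 ± 0.04. ADM rose by 4.55, CA9 by 3.46, BNIP3 by 3.02, LDHA by 2.66, P4HA1 by 2.48, KDM3A by 2.24, SLC2A1 by 1.49 and PDK1 by 0.95, and PGK1 rose too. VEGFA fell by 0.25 ± 0.05, from 25.9 ± 0.870 to 21.6 ± 1.29 FPKM (limma, adjusted p = 0.0016), but the call was lost after scaling by the median of ratios (-0.011, adjusted p = 0.846) and the direction turned when a length and GC trend was removed (0.206). HIF1A and EPAS1 changed by -1.07 and -1.53. MKI67, a proliferation marker, fell by 1.37, from 28.5 ± 0.667 to 10.4 ± 0.934 FPKM. ARNT had 8.20 ± 0.354 and 8.66 ± 0.254 FPKM and did not pass (adjusted p = 0.216), and its sign differed between scalings (-0.157 to 0.390). EGLN3, ANGPTL4, LOX, TXNIP and PCK1 lay under 1 FPKM on average and were not tested. The preset markers EGLN3, ANGPTL4 and LOX showed no rise, at 0.005, 0.017 and 0.088 FPKM in normoxia and 0.000, 0.014 and 0.039 in hypoxia. The HIF pathway core list was not called in KYSE410, with 4 of 13 genes higher and 5 lower (camera adjusted p = 0.7354).

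Further large rises in KYSE410 were ANKRD37, DEPP1, SLC2A3 and HSPA8, a constitutive heat shock protein gene, with log2 changes from 3.66 to 4.42. MIR7111 also rose by 4.07, but it lies inside RPL10A on the same strand (chromosome 6, 35470508 to 35470579), so its value is uncertain. CHAC1, EGR1, TRIB3 and IL1A had log2 changes of -3.94, -3.84, -3.56 and -3.41, and CEBPG, SESN2 and SLC7A11 of -3.35, -3.34 and -3.28. SLC35F6 fell by 3.36 but overlaps CENPA on the same strand (chromosome 2, 26764284 to 26781231). In total 3763 genes were higher and 6254 lower, of which 758 and 1848 changed by at least 1, and groups did not overlap for 84.6% of genes, against 10% by chance. The median change of all genes was -0.21; scaling by the median of ratios moved it to 0.00 and the calls to 5010 higher and 4998 lower, a higher share of 50.1% in place of 37.6%. Rescaling to a common sum moved them the other way, to a median of -0.46 with 2743 higher and 7497 lower.

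**Figure D2:**
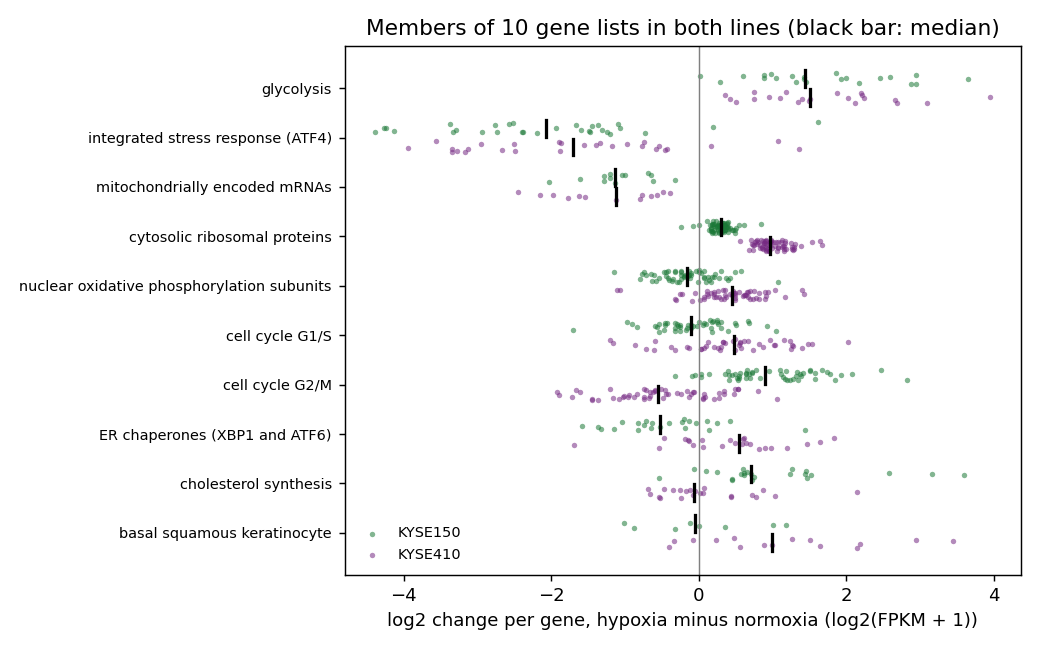
Log2 change per gene (hypoxia minus normoxia, log2(FPKM + 1), not relative to the median of all genes) for members of 10 lists in KYSE150 and KYSE410, with a black bar at each list's median. Glycolysis genes lay above 0 in both lines (21 of 22 and 22 of 22 called higher), and G2/M genes lay mostly above 0 in KYSE150 (48 of 54 higher) and below 0 in KYSE410 (36 of 54 lower).

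All 22 glycolysis genes rose in KYSE410 (median 1.71 above that of all genes, camera adjusted p = 3.412e-12, adjusted p = 0.217 with an estimated correlation), SLC2A3 by 3.94 and ALDOC by 3.10. Of 28 integrated stress response genes, 25 fell and 2 rose (median -1.71, against -0.21 for all genes, adjusted p = 2.602e-05, adjusted p = 0.217 with an estimated correlation). All 69 cytosolic ribosomal protein genes rose (relative median 1.18, adjusted p = 3.752e-26, adjusted p = 0.217 with an estimated correlation), although quantile normalization left 56 higher and 2 lower, with a median of 0.31. RPL28 rose by 1.67 and RPL7A by 1.65, and the group's share of all FPKM was 11.19 to 11.39% in normoxia and 18.54 to 19.04% in hypoxia. Of 58 nuclear oxidative phosphorylation genes, 45 rose and 6 fell (relative median 0.66, adjusted p = 1.540e-09, adjusted p = 0.217 with an estimated correlation), and quantile normalization left 39 higher and 10 lower, with a median of 0.29. By contrast, all 13 mitochondrially encoded mRNAs fell (relative median -0.91, adjusted p = 9.737e-04, adjusted p = 0.471 with an estimated correlation). Over all genes in this line the change fell with transcript length (Spearman rho -0.270 across genes), with a median of 0.44 up to 1000 nucleotides and -0.48 over 6000; in KYSE150 rho was 0.061.

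**Figure D3:**
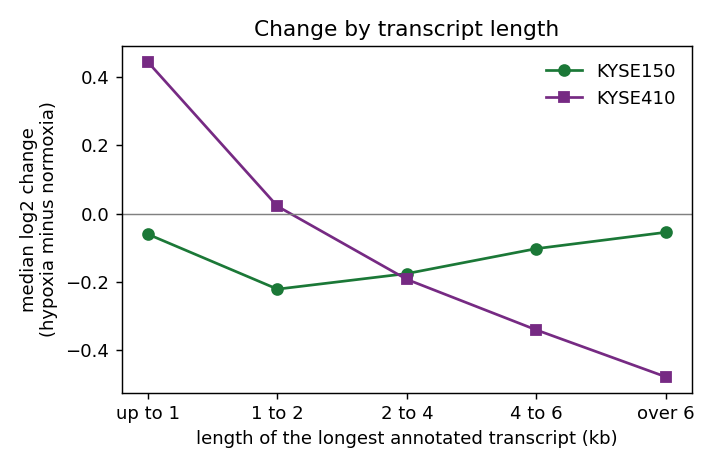
Median log2 change (hypoxia minus normoxia) of tested genes in 5 classes of transcript length (kb, longest annotated transcript) in KYSE150 (circles) and KYSE410 (squares). The KYSE410 medians fall from 0.44 in the shortest class to -0.48 in the longest, while those of KYSE150 lie between -0.22 and -0.05.

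Of 46 G1/S genes in KYSE410, 32 rose and 9 fell (adjusted p = 1.522e-05, adjusted p = 0.317 with an estimated correlation), among them ORC1, TYMS, RRM2 and MCM4 of DNA replication, by 1.39 to 2.03. Of 54 G2/M genes, 11 rose and 36 fell, and the list did not pass (relative median -0.34, adjusted p = 0.0822), although it did without hypoxia replicate 1 (adjusted p = 0.0494). Of 15 basal squamous keratinocyte genes, 12 rose and 3 fell (adjusted p = 6.185e-05, adjusted p = 0.217 with an estimated correlation), with the keratin genes KRT15, KRT17 and KRT14 up by 3.45, 2.94 and 2.18. Collagen and matrix genes rose in 18 of 23 cases, LOXL2 by 2.26, and fell in 5 (adjusted p = 2.336e-05, adjusted p = 0.255 with an estimated correlation). Heat shock genes rose in 13 of 19 cases, HSP90AB1 by 1.81, and fell in 5 (adjusted p = 4.790e-04, adjusted p = 0.255 with an estimated correlation). Of 24 ER chaperone genes, 15 rose, CALR by 1.64, and 6 fell, XBP1 by 1.69 (adjusted p = 6.968e-04, adjusted p = 0.371 with an estimated correlation). Adjusted over the list alone, the counts were identical for the lists named here for KYSE410, except for 46 higher oxidative phosphorylation genes. In all, 15 of 38 lists were called by camera and 0 held with an estimated correlation, under which 7 had an unadjusted p under 0.05; fry, which tests against 0, called 35. Another grouping of the 6 libraries also gave 15 called lists. The real grouping gave the smallest p of the 10 groupings for 10 of the 15. The lists for which it did not were oxidative phosphorylation, G1/S, MYC targets, replication-dependent histones and hypoxia-linked long noncoding RNAs.

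Across the 10951 genes tested in both lines, 1513 were higher in hypoxia in both and 3225 lower in both. Independent call lists of these sizes would share 798.3 and 2258.9 genes (Fisher's exact test for the higher genes, two-sided, odds ratio 4.929, p = 6.167e-251, across genes that are not independent). NDRG1, ANKRD37, ADM, CA9, BNIP3, KDM3A, P4HA1, LDHA and PGK1 were among the shared rises, and CHAC1, SESN2 and SLC7A11 among the shared falls. Genes called in opposite directions numbered 588 (higher in KYSE150 only) and 541 (higher in KYSE410 only), where independence would give 1346.7 and 1339.1. The log2 changes correlated at Pearson r = 0.593 and Spearman rho = 0.546 across genes. In both lines, 187 genes rose and 519 fell by at least 1. The excess of shared falls depends on scaling: 2318 genes were higher and 2332 lower in both lines after median-of-ratios scaling, and 2329 and 2490 after quantile normalization.

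The response differed between lines for many genes by the interaction test. Each such difference includes the KYSE410 change, so it cannot be told apart from a difference between library sets in that line. The difference was positive (KYSE410 minus KYSE150) for 3453 genes and negative for 4560, by at least 1 on the log2 scale for 700 and 1017. This balance depends on scaling, with 3987 positive and 3939 negative after median-of-ratios scaling and 2314 and 5958 after rescaling to a common sum. CYP1A1, a xenobiotic-metabolizing cytochrome, went from 2.47 ± 0.157 to 0.945 ± 0.200 FPKM in KYSE150 and from 11.5 ± 1.58 to 89.9 ± 6.20 in KYSE410, a difference in response of 3.71 ± 0.14. KRT15 differed by 3.24, but in KYSE150 it lay near 0 (0.074 FPKM in normoxia and 0.243 in hypoxia), so its difference rests on KYSE410. FABP5 differed by 2.66 and PSPH, which fell in both lines, by 2.63. FABP5 and PSPH have near-identical copies or pseudogenes, so their values are uncertain, as is SNRPN (3.36), which overlaps SNURF. In the other direction, EDN2 differed by -5.01 ± 0.19 and was listed at 0 in all 3 KYSE410 normoxia libraries. HBEGF, an EGF receptor ligand, did not pass in KYSE150 (1.98 ± 0.304 FPKM in hypoxia) and went from 24.6 ± 2.48 to 1.67 ± 0.282 in KYSE410 (difference -3.52). ARRDC4 and GAB2 differed by -3.46 and -3.06, and MKI67 by -3.04 ± 0.35.

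In the joint fit of all 12 libraries, which tests more genes and pools their spread, 1315 genes had a called difference and calls in opposite directions, 711 of them higher in KYSE150 and lower in KYSE410; 850 of the 1315 were also opposite after scaling by the median of ratios. Of 54 G2/M genes, 51 had a lower response in KYSE410 and 1 a higher one (median difference -1.51, camera adjusted p = 1.777e-17, adjusted p = 0.0608 with an estimated correlation). Of 24 ER chaperone genes, 19 had a higher response in KYSE410 (median difference 1.08, adjusted p = 1.231e-07, adjusted p = 0.0143 with an estimated correlation). All 19 oxygen-dependent histone demethylase genes had a lower response in KYSE410 (median difference -0.91, adjusted p = 7.694e-06, adjusted p = 0.449 with an estimated correlation). In KYSE150, 11 of the 19 rose and 3 fell (adjusted p = 0.0079, adjusted p = 0.685 with an estimated correlation). However, 7 of the 10 groupings of the KYSE150 libraries, the real one included, gave a camera p as small, so this call does not set the real grouping apart. In KYSE410 the list was not called (adjusted p = 0.231), and 14 genes fell, KDM4A by 2.13. With the length and GC trend removed 8 fell. The KYSE410 list median then moved from -0.47 to -0.05, and that of KYSE150 from 0.39 to 0.50, so the gap between lines depends on the processing. In all, 13 lists were called, while up to 19 were called after regrouping the libraries within each line. The real grouping gave the smallest p of 100 groupings for 1 of the 13, the ER chaperones, and a p matched by under 5% of groupings for 3. For the G2/M list 8 of 100 groupings, the real one included, gave a p as small. Regrouping also removes each line's oxygen effect, so these ranks do not test whether the response of a list differs between lines.

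In normoxia, 5115 genes were higher and 4904 lower in KYSE410 than in KYSE150, by at least 1 on the log2 scale for 1587 and 1830. KRT5, a basal keratin, had 168 FPKM in KYSE410 (n = 3) and was listed at 0 in all 3 KYSE150 libraries, as was MIR205HG against 92.1 ± 4.02. MAGEA4, a cancer-testis antigen gene, IL1A and the P-cadherin gene CDH3 were higher in KYSE410 by 7.30, 7.09 and 6.45. FOLR1, the folate receptor, had 1157 ± 126 FPKM in KYSE150 and 0.154 ± 0.076 in KYSE410. EEF1A2 and S100P were lower in KYSE410, with log2 differences of -8.40 and -7.80, as were CGA and UBB (-8.71), which has near-identical copies. Of 21 epithelial junction genes, 18 were higher in KYSE410 and 2 lower (camera adjusted p = 2.086e-05, adjusted p = 0.0879 with an estimated correlation). Of 48 G1/S genes, 41 were lower and 2 higher (adjusted p = 5.422e-10, adjusted p = 0.0879 with an estimated correlation). The sample-sheet numbers of the lines also differ here, so line and library set cannot be told apart.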

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

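The tests of transcript length, library set, scaling, replicate 2 and stress state in this part were chosen after the results were seen, and the counts over other splits of the libraries were planned. Each result given here was singled out because the response to hypoxia differed between KYSE410 and KYSE150 by a test of the difference itself (limma interaction, or camera on it). None of these differences can be told apart from a difference between library sets in KYSE410. Medians in this part are log2 changes as fitted, not relative to the median of all genes. Groups of 3 libraries were too small to test for single libraries far from the others.

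Among single genes, the response (KYSE410 minus KYSE150, log2) differed by 3.71 for CYP1A1, 3.36 for SNRPN, 3.32 for MIR7111, 3.24 for KRT15, 2.66 for FABP5 and 2.63 for PSPH. In the other direction it differed by -5.01 for EDN2, -3.52 for HBEGF, -3.46 for ARRDC4, -3.06 for GAB2 and -3.04 for MKI67. Among lists, the median difference was 1.08 for ER chaperones, 1.00 for basal squamous keratinocyte genes, 0.68 for heat shock proteins, 0.67 for cytosolic ribosomal proteins, 0.61 for G1/S genes and 0.57 for nuclear oxidative phosphorylation subunits. It was 0.56 for NRF2 targets, 0.48 for collagen and matrix modification, 0.29 for integrated stress response genes and 0.26 for the mitochondrial ribosome. It was -1.51 for G2/M genes, -0.91 for oxygen-dependent histone demethylases and -0.70 for cholesterol synthesis. With an estimated correlation, only the ER chaperone list held among these 13. KRT15 and the basal squamous keratinocyte list rest largely on KYSE410. KRT15 lay near 0 in KYSE150, and the basal list had 15 genes in the joint fit but 8 tested in KYSE150.

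Genes of the integrated stress response were lower in hypoxia in both lines. A difference between library sets in KYSE410 cannot be the whole cause of the fall in both lines, because it could not change KYSE150 values. In KYSE150 the median was at most -1.992 whichever library was left out. Its libraries carry consecutive numbers, 50 to 52 in normoxia and 53 to 55 in hypoxia, and a difference between these blocks was not tested. The KYSE410 median of -1.71 cannot itself be told apart from a difference between library sets, since no set there holds both oxygen levels. A trend with GC content and the length of the longest annotated transcript is argued against, since with it removed the higher of both medians was -1.349. Less endoplasmic reticulum stress in hypoxia stays open in both lines: the ER chaperone median was 0.542 in KYSE410, where members went both ways and the call was lost with an estimated correlation (adjusted p = 0.371), and -0.519 in KYSE150, where the list was not called. A nutrient or density state of the normoxic cultures that raised these genes there could also give this pattern and stays untested: 0 samples have labels that describe medium or density.

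G2/M genes were higher in hypoxia in KYSE150 and had a lower response in KYSE410. KYSE150 normoxia replicate 2 is argued against as the cause, because the KYSE150 median was 0.806 without it. A trend with GC content and the length of the longest annotated transcript is argued against. The median difference between lines was -1.585 with it removed. In KYSE410 the median of -0.552 cannot be told apart from a difference between library sets, since no set holds both oxygen levels, and its size depends on the processing, being -0.31 after median-of-ratios scaling and -0.26 with the length and GC trend removed. A true difference between the lines stays open as well.

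All 69 cytosolic ribosomal protein genes were higher in hypoxia in KYSE410. With a length and GC trend removed the median was 1.021. This does not decide whether transcript length was the whole cause. The trend used each gene's longest annotated transcript, which need not be the one that the cells express. Scaling is argued against as the cause of the direction, because at least 56 of the 69 were called higher under each of 5 scalings, but the size depends on it: the median was 0.97 as deposited and 0.31 after quantile normalization. A difference between library sets in KYSE410 could account for the pattern and cannot be told apart from oxygen there: no KYSE410 set holds both oxygen levels, and the count called higher in KYSE150 does not decide, being 19 as deposited, 51 after median-of-ratios scaling, 67 without KYSE150 normoxia replicate 2 and 3 without any other single library. In KYSE150 the share of all FPKM taken by these genes was 13.72 to 16.65% in normoxia and 18.21 to 18.39% in hypoxia. A response of the cells stays open beside a difference between library sets.

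Other splits of the libraries were counted for each model. In KYSE150 the real grouping called 7906 genes and the highest other 0, and in KYSE410 10017 and 0; 10 splits are too few for a share under 0.05. The normoxia libraries, fitted alone, gave 9423 genes between lines against 0 at most for another split, again with 10 splits, too few for such a share. For gene lists, the real grouping called 16 in KYSE150 with 16 as the highest other, and 15 in KYSE410 with 15, and 10 splits are too few here as well. Genes called in both lines in 1 direction numbered 4738 (highest other 1129, 1 of 100 splits as large, the real one included). Genes with a different response numbered 8013 (highest other 9940, 2 of 100 splits as large). For the latter, the other split as large kept both lines' real groups and reversed the oxygen labels of KYSE410. Regrouping also removes each line's oxygen effect, which by itself lowers both counts. These splits therefore do not test whether the lines respond alike or differently, and do not exclude chance for either count. Chance was not excluded for the number of lists with a different response: the real value was 13, the highest other was 19, and 57 of 100 splits gave as many. The number of lists with a different response is therefore no evidence in itself.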

How the results depend on the processing

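The length and GC trend, median-of-ratios scaling of single genes and their counts (it was planned for gene lists), rescaling to a common sum, array weights and the set without mitochondrial and ribosomal protein genes were chosen as tests after the data were seen; the others were planned. Count-based alternatives were not run because the values are not counts. Of the counts under alternatives, 254 stayed within 1.5 times the main count and 24 moved further. With a mean of at least 5 FPKM, where fewer genes are tested, 3253 genes were lower in KYSE150, 4007 in KYSE410 and 2010 in both; 2981 had a negative difference in response (KYSE410 minus KYSE150), and 3400 and 3208 were higher and lower in KYSE410 in normoxia. Requiring a log2 change of at least 1, which can only remove calls, left 570 and 980 genes in KYSE150, 758 and 1848 in KYSE410, 187 and 519 in both lines, 700 and 1017 with a positive and negative difference in response, and 1587 and 1830 in normoxia. Genes higher in both lines numbered 2329 after quantile normalization, 2318 after median-of-ratios scaling, 2576 with the length and GC trend removed and 2520 with the replicate block as well; the cause was not tested. An estimated correlation left 1 list called in KYSE150 and 0 in KYSE410 (7 lists in each line had an unadjusted p under 0.05), and fry, which tests against 0 and not against other genes, called 31 and 35. VEGFA in KYSE410 turned to 0.206 with the length and GC trend removed, with or without the replicate block, and ARNT in KYSE410 to -0.157 after rescaling to a common sum; the cause was not tested. Lists that camera did not call had the other direction in fry: in KYSE150 G1/S (adjusted p = 0.0059), NF-kB (6.279e-04) and Notch, Wnt and TGF-beta feedback (0.0248), and in KYSE410 the mitochondrial ribosome (4.555e-04), DNA repair (8.228e-04), immediate early genes (0.0267), NRF2 targets (2.478e-04) and p53 targets (4.858e-05). Among values of named genes, 4606 kept direction and side of the threshold, 33 lost the call, 9 gained it and 3 reversed; among lists these numbers were 911, 43, 52 and 8. Leaving out a library gave 2454 to 3661 higher and 4169 to 5756 lower genes in KYSE150, 3538 to 3761 and 5995 to 6220 in KYSE410, 1296 to 1919 and 2804 to 3790 in both lines, 3153 to 3738 and 4187 to 4919 with a positive and negative difference in response, 4804 to 5294 and 4692 to 5018 in normoxia, and 16 to 19 and 15 to 17 lists. Without KYSE150 normoxia replicate 2, collagen and matrix modification was no longer called in KYSE150 (adjusted p = 0.0909), while ER chaperones (0.0244), heat shock proteins (0.0380) and pH regulation (0.0416) were. Replicate numbers do not pair the libraries by their values (correlations of same-numbered deviations -0.069 to 0.084), and the block gave 2922 and 4835 genes in KYSE150 and 3730 and 6201 in KYSE410. Array weights stopped before their tolerance was reached. Depth is unknown, so its limit on low values cannot be given.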

Other observations

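Replication-dependent histone genes rose in 12 of 25 cases in KYSE150 and 17 of 23 in KYSE410, with 2 falls in each (camera adjusted p = 5.104e-04 and 2.602e-05, adjusted p = 0.156 and 0.217 with an estimated correlation). Their median in normoxia was low, 1.88 FPKM in both lines, and how completely the mRNA beads captured them was not tested. In each line 2 of 10 groupings, the real one included, gave a camera p as small. H2BC5 rose by 2.18 in KYSE150 and 2.54 in KYSE410. Hypoxia-linked long noncoding RNAs rose in 5 of 10 cases in KYSE150, such as MIR210HG by 2.91 and H19 by 2.07, and in 9 of 10 in KYSE410, such as MALAT1 by 1.65 and NEAT1 by 1.61 (adjusted p = 0.0197 and 4.637e-04, adjusted p = 0.351 and 0.217 with an estimated correlation). There was 1 fall in each line. In KYSE410, 2 of 10 groupings, the real one included, gave a camera p as small for this list. In KYSE410, 26 of 38 MYC target and ribosome biogenesis genes fell and 6 rose (adjusted p = 0.0293, adjusted p = 0.482 with an estimated correlation). For this list 3 of 10 groupings, the real one included, gave a camera p as small. The hypoxia metagene had 30 of 49 genes higher and 16 lower there (adjusted p = 7.323e-05, adjusted p = 0.238 with an estimated correlation).

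In KYSE150, 13 of 24 fatty acid and lipid storage genes and 8 of 13 mesenchymal genes rose, VIM by 1.03 and ITGA5 by 2.01, while 4 and 1 fell (adjusted p = 0.0044 and 0.0030, adjusted p = 0.156 for both with an estimated correlation). Of 69 cytosolic ribosomal protein genes in this line, 19 were called higher over all genes and 2 adjusted over the list alone, and 0 lower (adjusted p = 1.955e-06, adjusted p = 0.715 with an estimated correlation). For this list 4 of 10 groupings, the real one included, gave a camera p as small. Under other scalings 29 (quantile normalization, with 4 lower) to 51 (median of ratios, with 0 lower) were called higher. The count rests on KYSE150 normoxia replicate 2, in which these genes took 16.65% of all FPKM against 13.99 and 13.72% in the other normoxia libraries. Without it 67 were called higher (median 0.44), and without any other single library 3 (median 0.20 without normoxia replicate 3). In the KYSE150 hypoxia libraries their share was 18.21 to 18.39%, above that of each normoxia library. Of 14 reference genes in KYSE410, 8 rose, GAPDH by 2.02, and 3 fell, TBP by 1.38 among them (adjusted p = 0.0133, adjusted p = 0.255 with an estimated correlation), a call lost after quantile normalization, which left 6 higher and 5 lower. Adjusted over the list alone, the other counts in this part were identical.

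Markers of other cell types were low in most cases. Of the fibroblast markers in the tables, 2 of 12 were above 1 FPKM in KYSE150 normoxia and 1 in hypoxia, COL1A1 at 5.89 and 4.64 FPKM, and 0 of 10 in KYSE410. Of the endothelial markers, 2 of 9 and 1 of 9 were in KYSE150, ESAM at 22.2 and 18.7 FPKM, and 0 of 9 in KYSE410. Of the immune cell markers, 1 and 3 of 11 were in KYSE150 and 1 and 2 of 10 in KYSE410, with CD68 at 16.3 and 28.4 FPKM in KYSE150 and 31.5 and 83.4 in KYSE410.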
